A study of Mus musculus with 17 samples.

How the data were processed

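Total RNA of BHK21 cells, knocked down for Cirp or control, taken at 24, 48 and 72 h of culture, was read on 17 one-colour (Cy3) NimbleGen arrays of mouse sequences. The groups were control and Cirp knockdown at each time, with 3 arrays each and 2 for the knockdown at 24 h; the third array of that group was not used here. The times of the control arrays follow the sample titles, since a second label field gives 42 h for those titled 48 and 72 h. Slide and scan of each array are not given in the sources used here.

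The deposited values are RMA intensities, made by the authors per the submitters' processing notes, with the software version not given in the sources used here. RMA corrects background, normalizes between arrays and summarises the probes of a target sequence. The intensities are on a linear scale, and log2 was taken without an offset or a filter. Of 44170 target sequences, 44155 were summarised from 3 probes and 15 from 1 or 2. One further row of 5000 random-sequence probes served as the background and was not tested. The series-wide value table held the same values as the array files (largest difference 0). A gene identifier was given for 41886 target sequences, of which 39057 were found in the mouse gene reference, and 5650 symbols were updated from it. Of the 24171 symbols, 10215 had more than 1 target sequence. The mean log2 of a target sequence over all arrays had a median of 6.16, and 87.1% of the target sequences had a mean above the random-sequence row. The 1049 chemoreceptor sequences had a median of 5.44. The column of standard errors in the array files is undefined and was not used.

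A linear model with a mean per group was fitted to all 17 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, default settings, two-sided moderated test), which pools the spread of the groups with 11 residual degrees of freedom. The comparisons were knockdown against control at each time and over all times (the mean of the 3 differences), the interaction of knockdown and time (moderated F test), and 48 and 72 h against 24 h within each arm. P-values were adjusted by Benjamini-Hochberg over the 44170 target sequences, with a threshold of 0.05. The median SE of a difference was 0.46 at 24 h, 0.41 at 48 and 72 h, and 0.24 over all times. Where leaving out an array left a group with a single array, that array was assumed to vary like the other groups. Where the lower group's mean lay at the random-sequence background, a fold is given as a lower bound against that background. The median difference over all target sequences was under 0.1 in size in every comparison. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

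Gene lists were tested with limma's camera at a preset correlation of 0.01, on the brightest target sequence of each of the 24171 genes, adjusted over the 28 lists within a comparison; camera with an estimated correlation and fry were run beside it. The tests made 168 list results over 6 comparisons, of which 73 passed and 12 passed with an estimated correlation. The 28 lists covered the circadian clock, RNA-binding cold and stress proteins, G1/S and DNA replication, G2/M and mitosis, p53 targets and CDK inhibitors, apoptosis regulators, ERK feedback and immediate early genes, NF-kB and inflammatory genes, interferon-stimulated genes, cytosolic ribosomal proteins, translation factors, splicing factors, the unfolded protein response with ATF4 targets, heat shock and chaperones, oxidative stress and thioredoxin, hypoxia and glycolysis, oxidative phosphorylation, cholesterol and fatty acid synthesis, extracellular matrix and TGF-beta response, DNA damage repair, the proteasome, cell adhesion and cytoskeleton, olfactory receptors as background, and markers of fibroblasts, kidney tubule epithelium, endothelium, myofibroblasts with smooth muscle, and macrophages with leukocytes. The comparisons, tests, these lists and the rule for named genes were fixed before the data were examined. After the data had been seen, 10 lists were added and tested the same way, adjusted over those 10: neuron, oligodendrocyte, astrocyte, macrophage (a longer list), MHC class I, erythroid, mesothelium, simple epithelium and junction, skeletal muscle, and HOX genes. Of all list symbols, 44 were not on the array and were left out.

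Named genes are those with a single symbol whose higher group mean reached the median level, other than provisional gene symbols and chemoreceptors. For knockdown against control they were the 10 largest increases and 10 largest decreases past the threshold whose arrays did not overlap between the arms; over all times, the knockdown mean had to lie on the same side at each time. For the interaction they were the 5 smallest p, for the time comparisons the 5 largest changes each way, and from each list up to 4 members past the threshold with the smallest p, or 2 with none past it. Cirbp and Rbm3 were always named. A gene with several target sequences was named by that with the smallest p. Members of the added lists, and Uba1, Rpl7 and Hoxd9, were chosen after their values were seen.

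The procedure was tested on simulated data: independent normal noise with each target sequence's own residual SD, and differences added to 200 target sequences above the median level. Of differences of log2 size 2, limma recovered 44% at 24 h, 56% at 48 h, 57% at 72 h, 92% over all times and 6% in the interaction, and of size 1 it recovered 2%, 6%, 7% and 40% in the first 4 of these; at most 4 unchanged target sequences were called. Camera recovered the moved proteasome list and called 0 of 27 unmoved lists, but noise independent between genes cannot test calls of correlated lists. Over 40 pairs of arrays with the same replicate number in different groups, the correlation of deviations from the group mean had a median of 0.016 (-0.37 to 0.27, 7 pairs over 0.1), against -0.011 for pairs with other numbers, and 9 of 17 arrays correlated best with an array of their own number. The labels do not say that numbers pair the arrays, and the numbers were used as a block as an alternative.

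Alternatives set beforehand were median centring, cyclic loess, filters on level, trend and robust settings, array weights, fits on the compared groups alone, the replicate block, 1 target sequence per gene, a minimum log2 difference of 1, fry, the estimated correlation, the mean of a gene's target sequences, and leaving out each array. After seeing the data, these were added: the neuron and macrophage marker means as covariates, leaving out the 4 arrays brightest in macrophage markers, leaving out a time, and removal of the trend with genomic span from each array (loess of span 0.3 in 8 bins of level). A first form of that correction, without the bins, left a trend and was replaced after its result was seen.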

Results

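Gene expression was measured in BHK21 cells, a line derived from baby hamster kidney, in which the cold-inducible RNA-binding protein Cirp (gene symbol Cirbp) had been knocked down, and in control BHK21 cells. Cirp is an RNA-binding protein whose synthesis rises when cells are mildly cooled. Cells of each arm were taken at 24, 48 and 72 h, and total RNA was read on 17 one-colour arrays that carry mouse sequences. There were 3 arrays in each arm at each time, except for the knockdown at 24 h, where 2 arrays were used. Each array read 44170 target sequences, and those with a gene name covered 24171 gene symbols. The median log2 intensity of an array lay between 6.21 and 6.31, and 72.0% to 81.6% of the target sequences on an array exceeded the row of random-sequence probes, which measures background. The knockdown arrays at 72 h had the lowest shares, 72.0% to 73.4%. Pearson's r between arrays of one group, across target sequences that are not independent replicates, ran from 0.887 to 0.904 in the knockdown at 72 h and from 0.921 to 0.963 in the other groups. The organism label gives mouse while the line is of hamster origin, so a low signal can also stand for a hamster transcript that the mouse probes do not read. Differences are knockdown minus control on the log2 scale, given ± SE unless stated, with n = 3 per group except n = 2 for the knockdown at 24 h; positions are on the mouse build MM9. The p-values measure the spread between these arrays only, since the labels do not say whether the replicates were separate cultures, and each arm is a single cell population. The number of arrays limits the precision.

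The first question was whether Cirbp was lower in the knockdown cells. Cirbp (target sequence BC075699, chromosome 10, 79630595 to 79634400) was among the brighter sequences in the control cells, with log2 intensities of 13.03 ± 0.15 (SD, n = 3) at 24 h, 13.14 ± 0.19 at 48 h and 12.97 ± 0.11 at 72 h. In the knockdown cells it read 12.38 ± 0.28 (SD, n = 2), 11.92 ± 0.39 (n = 3) and 12.21 ± 0.18 (n = 3). Over all times Cirbp fell by 0.87 ± 0.15 (adjusted p = 0.0011), which left 54.7% of the control intensity (95% interval 44.1% to 67.8%). The labels call these cells knockdown and also mark them -/-, the sign of a null genotype; the signal that remained does not show loss of the transcript. All 8 knockdown arrays lay below every control array of their time. At 48 h it fell by 1.22 ± 0.24 (adjusted p = 0.0079) and at 72 h by 0.75 ± 0.24 (adjusted p = 0.0458), while the difference of -0.65 ± 0.27 at 24 h did not pass (adjusted p = 0.313). The interaction test did not show that the size of the decrease differed between times (adjusted p = 0.536). The 72 h call was lost on leaving out any of the 6 arrays at 72 h (adjusted p 0.057 to 0.131), and the 48 h call was lost without replicate 1 of the knockdown at 48 h (adjusted p = 0.0535). The call over all times was lost with the mean intensities of neuron and macrophage markers as covariates (-1.08, adjusted p = 0.157) and without the 4 arrays brightest in macrophage markers (-0.77, adjusted p = 0.0527), in a range over its alternatives of 4.07e-04 to 0.157. Rbm3, the sister cold-inducible protein, was read by 5 target sequences, and 1 of them, BC086491, rose at 72 h by 0.97 ± 0.20 (adjusted p = 0.003). The other 4 Rbm3 sequences differed at 72 h by 0.01, 0.33, 0.49 and 0.65 and did not pass.

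**Figure D1:**
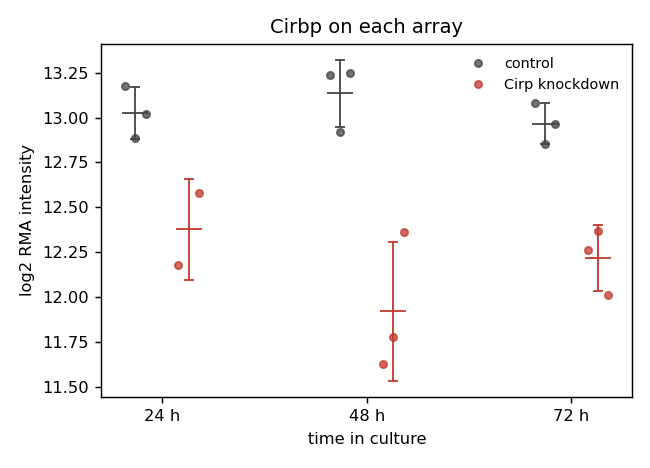
Log2 RMA intensity of Cirbp on each array against time in culture, for control (grey) and Cirp knockdown (red) cells; horizontal lines are group means and bars the SD (n = 3, and n = 2 for the knockdown at 24 h). All 8 knockdown points lie below the control points of their time.

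Transcripts of brain cells and of macrophages were present at levels that differed between arrays of one group, and they moved with several gene groups. The mean log2 intensity of 22 neuron markers was 9.89 to 10.03 on the control arrays at 48 h, against 7.12 to 7.89 on those at 72 h. On the control arrays at 24 h it was 8.89 in replicate 1 and 7.13 and 6.87 in the other two, and on the knockdown arrays at 48 h it was 9.24 in replicate 3 and 6.96 and 7.15 in the other two. The mean of 19 macrophage markers was high where the neuron mean was low in those groups: 8.48 and 8.27 in control replicates 2 and 3 at 24 h against 7.04 in replicate 1, and 8.52 and 7.96 in knockdown replicates 1 and 2 at 48 h against 6.75 in replicate 3. The levels were measured after the data had been seen, and no label names brain or blood cells.

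**Figure D2:**
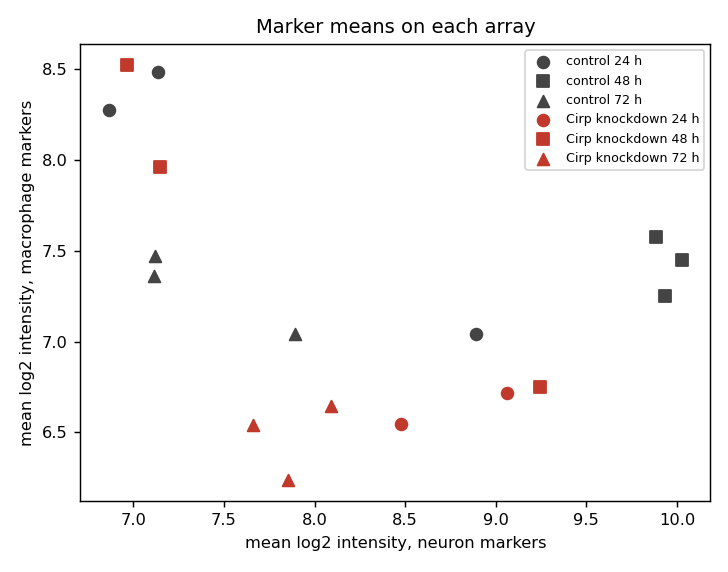
Mean log2 intensity of 19 macrophage markers against that of 22 neuron markers; each point is an array, coloured by arm and shaped by time. The control arrays at 48 h lie at 9.89 to 10.03 on the neuron axis, and arrays of the control group at 24 h and of the knockdown group at 48 h lie far apart.

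The comparison asked how the arms differed at 24 h. Krt8, a keratin of simple epithelia, rose by 5.48 ± 0.31 (adjusted p = 3.63e-07), and Upk3b, a surface protein of urothelium and mesothelium, rose by 5.41 ± 0.30 (adjusted p = 3.63e-07) from a control mean of 5.41, near the background of 5.34. Aebp1, a secreted regulator of collagen assembly, fell by 4.63 ± 0.50 (adjusted p = 2.28e-04), and Chrng, the gamma subunit of the fetal muscle acetylcholine receptor, fell by 3.93 ± 0.27 (adjusted p = 1.98e-06). Of the 44170 sequences, 361 were higher and 165 lower past the threshold, 68.6% higher, against 51.3% in the brightest 25% alone and 53.6% with trend and robust settings. Lsr, a component of tricellular junctions, rose by 4.75, Aldh1a2, the retinoic acid synthesis enzyme of mesothelium, by 4.44, and the cadherin Cdh3 by 4.19. The junction protein Lmo7 rose by 4.23 and the LIM protein Crip1 fell by 3.90. Pam, an enzyme of peptide amidation (4.46), the matrix protein Tnc (-3.26) and the nucleoside transporter Slc29a1 (-2.96) passed as well, but each lost its call without replicate 2 of the knockdown (adjusted p 0.0624, 0.105 and 0.0526). Uba1y on chromosome Y (BC140444, 157263 to 179963) was the largest difference, at 6.79 ± 0.30, and the pseudogene Rpl7-ps8 rose by 4.89 ± 0.39. Which hamster transcript these read is uncertain, since target sequences of the near-identical genes Uba1 (BC058630 and BC145984, but not AK143416) and Rpl7 were bright in both arms.

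Of the 28 lists fixed beforehand, 7 passed the list test at 24 h, and none held with an estimated correlation between genes. Among 41 genes of the extracellular matrix and TGF-beta response, 5 fell, 0 rose and 36 did not pass (adjusted over the list alone, 12 fell and 1 rose), and the list was lower (adjusted p = 1.22e-04, and adjusted p = 0.416 with an estimated correlation). Its falling members included Tgfbi (-2.91), the matrix protease Mmp14 (-1.26) and Col3a1 (-1.13), a fibrillar collagen. Mmp14 and Col3a1 lost their calls on leaving out any of the 5 arrays (up to 0.301 and 0.314), and Tgfbi without control replicate 2 or 3 or either knockdown array (up to 0.225). The fibroblast markers, which share collagens with that list, were lower (1 of 12 fell, 11 did not pass and 3 fell adjusted over the list alone; adjusted p = 0.0118, and adjusted p = 0.416 with an estimated correlation). Oxidative phosphorylation genes were lower too (1 of 36 fell, also adjusted over the list alone; adjusted p = 0.0118, and adjusted p = 0.416 with an estimated correlation). Cytosolic ribosomal proteins were lower as a list (adjusted p = 0.044, and adjusted p = 0.563 with an estimated correlation), though 1 of 50, Rpl8, rose by 2.14 ± 0.24 and none fell; adjusted over the list alone, 3 rose and 1 fell. Translation factors were higher (adjusted p = 0.036, and adjusted p = 0.563 with an estimated correlation) with 0 of 30 members past the test. Interferon-stimulated genes (adjusted p = 0.0387, and adjusted p = 0.563 with an estimated correlation) and macrophage and leukocyte markers (adjusted p = 0.036, and adjusted p = 0.547 with an estimated correlation) were lower, with 0 of 31 and 0 of 9 members past the test, also adjusted over the list alone. They moved with the macrophage mean, 8.48 and 8.27 on control replicates 2 and 3 against 6.72 and 6.55 on knockdown arrays. Their direction turned with both marker scores as covariates (adjusted p = 0.855 and 0.998), which cannot test macrophage markers, as 1 score is theirs. The matrix list kept its call on leaving out each array, with 0.0064 as the highest adjusted p, and lost it with the scores as covariates (0.131) and without the 4 arrays brightest in macrophage markers (0.112). The splicing factors Hnrnpk, an RNA-binding protein (2.09 ± 0.26), and Sf3b1, part of the branch-site complex (1.83 ± 0.26), rose without a call for their list.

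The other 6 lists with a call at 24 h each lost it on leaving out some array. Oxidative phosphorylation lost it without knockdown replicate 1 (0.0794), the fibroblast markers without control replicate 2 or knockdown replicate 1 (up to 0.161), and ribosomal proteins without control replicate 2 or 3 or knockdown replicate 1 (up to 0.364), as well as after cyclic loess (0.157). Translation factors lost it without control replicate 1 or 2 or either knockdown array (up to 0.161). Interferon-stimulated genes (up to 0.318) and macrophage markers (up to 0.161) lost it without control replicate 2 or 3 or either knockdown array. With the marker scores as covariates, and without the 4 arrays brightest in macrophage markers, oxidative phosphorylation (0.0551 and 0.112), fibroblast markers (0.0744 and 0.262) and ribosomal proteins (0.0744 and 0.753) lost their calls, and translation factors lost theirs without the 4 arrays (0.0578). Ribosomal proteins also lost it with the span trend removed (0.409). The 526 sequences became 255 without control replicate 2, 187 without control replicate 3, 223 without knockdown replicate 1 and 98 without knockdown replicate 2. They became 67 with the marker scores as covariates.

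At 48 h the question was the same. Krt8 rose by 5.90 ± 0.28 (adjusted p = 3.86e-08), Krt7, another keratin of simple epithelia, by 4.99 ± 0.43 (adjusted p = 9.35e-06), and Upk3b by 4.71 ± 0.27 (adjusted p = 1.58e-07) from a control mean of 5.43, near the background of 5.29. Gpc3, a heparan sulfate proteoglycan of the cell surface, rose by 5.54 ± 1.01 (adjusted p = 0.0044), from 7.10 ± 0.23 (SD) in control to 12.64 ± 0.24 (SD) in knockdown cells. Bmp4, a growth factor of the TGF-beta family, rose by 4.61 ± 0.30 (adjusted p = 6.5e-07) and Hoxc10, a homeobox gene of the posterior body, by 4.61 ± 0.48 (adjusted p = 5.4e-05), at least 17.5-fold over a control mean at the background. Most of the 10 named genes that fell are known from brain. Mbp and Mobp, proteins of myelin, fell by 5.15 ± 0.51 (adjusted p = 3.22e-05) and 5.31 ± 0.77 (adjusted p = 8.13e-04), and Slc17a7, which loads glutamate into synaptic vesicles, by 5.06 ± 0.56 (adjusted p = 8.48e-05). Slc1a2, the glial glutamate transporter (-5.02), the kinase Prkcb (-4.37) and Gpr37l1, a glial receptor (-4.36), fell together with Nrsn1 (-4.45), Rapgef4 (-4.42) and Chgb (-4.30), a protein of secretory granules. They moved with the neuron marker mean, which was 9.89 to 10.03 on the control arrays and 6.96, 7.15 and 9.24 on the knockdown arrays. The muscle gene Chrng, which is not a brain gene, fell by 4.45 ± 0.24 (adjusted p = 1.58e-07). Col14a1, a fibril-associated collagen, rose by 5.04 from a control level at the background, at least 26.0-fold, and the calmodulin-like gene Calml4 by 4.76. Uba1y (7.53) and Rpl7-ps8 (5.78) were again among the largest increases.

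Of the fixed lists, 16 passed at 48 h, 14 of them higher in the knockdown; heat shock and cholesterol synthesis held with an estimated correlation. Of 22 heat shock and chaperone genes, 7 rose and 0 fell (adjusted over the list alone, 8 rose; adjusted p = 4.72e-05, and adjusted p = 0.0122 with an estimated correlation); examples were Hspb1, a small heat shock protein (2.07 ± 0.22), and Hspd1, the mitochondrial chaperonin (1.40 ± 0.24). Of 33 genes of cholesterol and fatty acid synthesis, 8 rose and 0 fell (adjusted over the list alone, 15 rose; adjusted p = 1.59e-06, and adjusted p = 0.0295 with an estimated correlation), among them Fasn, the fatty acid synthase (1.79 ± 0.23), and Msmo1, a sterol oxidase (2.23 ± 0.29). Proliferation genes were higher. Of 36 genes of G1/S and DNA replication, 8 rose and 0 fell (9 adjusted over the list alone; adjusted p = 1.59e-06, and adjusted p = 0.135 with an estimated correlation). The kinase Cdk2 rose by 2.09 ± 0.35 and the helicase subunit Mcm2 rose by 1.61 ± 0.31. Of 33 genes of G2/M and mitosis, 8 rose and 0 fell (adjusted over the list alone, 17 rose and 1 fell; adjusted p = 3.95e-07, and adjusted p = 0.111 with an estimated correlation). Tpx2, a spindle assembly factor, rose by 3.12 ± 0.38. Cell adhesion and cytoskeleton genes were higher, 6 of 35 rising and 0 falling (12 adjusted over the list alone; adjusted p = 5.06e-05, and adjusted p = 0.113 with an estimated correlation), among them Tpm2, a tropomyosin (2.72 ± 0.27), and Vasp, an actin regulator (2.35 ± 0.26).

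Stress and growth lists were higher at 48 h as well. Oxidative stress genes had 7 of 29 members up and 0 down (11 adjusted over the list alone; adjusted p = 1.98e-04, and adjusted p = 0.135 with an estimated correlation). Prdx3, a mitochondrial peroxidase, rose by 2.47 ± 0.37. Unfolded protein response genes had 5 of 30 up and 0 down (adjusted over the list alone, 6 rose and 1 fell; adjusted p = 0.0143, and adjusted p = 0.197 with an estimated correlation). The stress regulator Atf4 rose by 1.39 ± 0.22. Apoptosis regulators had 5 of 26 up, including the death receptor Tnfrsf1a (1.62 ± 0.22) and the survival protein Mcl1 (1.35), and 0 down (5 adjusted over the list alone; adjusted p = 0.0208, and adjusted p = 0.135 with an estimated correlation). Targets of p53 and CDK inhibitors had 3 of 25 up, among them Cdkn1a, which blocks the cell cycle (1.55 ± 0.23), and 0 down (adjusted over the list alone, 4 rose and 1 fell; adjusted p = 0.0288, and adjusted p = 0.253 with an estimated correlation). Translation factors had 4 of 30 up and 0 down (5 adjusted over the list alone; adjusted p = 0.0029, and adjusted p = 0.197 with an estimated correlation). Eif2b5 rose by 2.34. DNA repair genes had 3 of 33 up, with H2ax, the histone that marks breaks, at 1.78, and 0 down (3 adjusted over the list alone; adjusted p = 0.0029, and adjusted p = 0.135 with an estimated correlation). Proteasome subunits had 1 of 29 up, Psma6 (1.37 ± 0.20), and 0 down (3 adjusted over the list alone; adjusted p = 0.0098, and adjusted p = 0.135 with an estimated correlation). Hypoxia and glycolysis genes had 3 of 33 up and 1 down (adjusted over the list alone, 5 rose and 1 fell; adjusted p = 0.0098, and adjusted p = 0.194 with an estimated correlation); Car9, an acid-regulating anhydrase, rose by 3.77 ± 0.41, at least 11.7-fold over a control mean at the background, and Aldoc, an aldolase abundant in astrocytes, fell by 3.45 ± 0.54.

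The remaining lists at 48 h had at most 1 member past the test. Interferon-stimulated genes were higher with 0 of 31 past the test, also adjusted over the list alone (adjusted p = 0.0048, and adjusted p = 0.312 with an estimated correlation), beside macrophage means of 8.52, 7.96 and 6.75 on the knockdown arrays against 7.25 to 7.58 in control, and their direction turned with the marker scores as covariates (0.659) and without the 4 arrays brightest in macrophage markers (0.933). Clock genes were lower, 1 of 20 falling, the same adjusted over the list alone (adjusted p = 0.0175, and adjusted p = 0.111 with an estimated correlation); this was Hlf, a clock output factor also expressed in brain (-3.17 ± 0.56). Oxidative phosphorylation was lower with 1 of 36 falling, also adjusted over the list alone (adjusted p = 0.0354, and adjusted p = 0.253 with an estimated correlation), and lost its call without control replicate 1 or 3 or knockdown replicate 1 or 3 (up to 0.107). The p53 list lost it without control replicate 2 or knockdown replicate 1 or 2 (up to 0.139). Cyclic loess, which rescales the arrays to one another, ended the calls of p53 targets (0.0837), apoptosis (0.059), the unfolded protein response (0.0975) and the proteasome (0.0981). Removing the span trend ended those of p53 targets (0.095), apoptosis (0.07), translation factors (0.0556), the unfolded protein response (0.122), hypoxia and glycolysis (0.095) and the proteasome (0.186). With the marker scores as covariates replication, heat shock, cholesterol synthesis and DNA repair kept their calls (adjusted p = 0.025 each), and the other 12 lists lost theirs. Without the 4 arrays brightest in macrophage markers DNA repair (0.0799), translation factors (0.0594), apoptosis (0.326), p53 targets (0.788), hypoxia and glycolysis (0.457), the unfolded protein response (0.321) and oxidative phosphorylation (0.135) lost their calls. At 48 h 1506 sequences were higher and 978 lower, 60.6% higher as deposited, 47.5% after cyclic loess and 50.5% with the trend with genomic span removed, so no direction of the whole is given. The 2484 became 1606 without control replicate 2, 1413 without control replicate 3, 1146 without knockdown replicate 1 and 1122 without knockdown replicate 2. They became 19 with the marker scores as covariates.

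At 72 h the knockdown cells differed most widely from their controls. Krt8 rose by 7.39 ± 0.28 (adjusted p = 2.94e-09), at least 143-fold over a control level at the background, and Gpc3 by 7.69 ± 1.01 (adjusted p = 5.93e-05). Ephb4, a receptor of the ephrin family, rose by 5.33 ± 0.28 (adjusted p = 2.27e-08) and Krt7 by 6.13 ± 0.43 (adjusted p = 2.2e-07). The matrix genes Aebp1, which read 14.08 ± 0.06 (SD) in control cells, and Tnc fell by 6.71 ± 0.44 (adjusted p = 1.46e-07) and 6.70 ± 0.50 (adjusted p = 3.79e-07). Gja1, the gap junction protein connexin 43, fell by 5.21 ± 0.29 (adjusted p = 2.84e-08), Pfkfb3, which drives glycolysis, by 5.38 ± 0.27 (adjusted p = 2.2e-08), and Arhgap1, a GTPase-activating protein, by 5.43 ± 0.22 (adjusted p = 4.56e-09). Hspg2, the basement membrane proteoglycan perlecan, fell by 5.32, Slc16a3, a lactate exporter, by 5.89, the ion cotransporter Slc12a7 by 5.52, Rhobtb1 by 5.36 and Dact1, a Wnt antagonist, by 5.13. Col14a1 rose by 5.36, at least 32.5-fold, Calml4 by 5.72, the ubiquitin ligase subunit Fbxo2 by 5.58 and Pam by 5.55, although another Pam sequence, AK132581, fell by 1.83. Uba1y (6.12) and Rpl7-ps8 (6.62) rose again.

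Of the fixed lists, 10 passed at 72 h, and proteasome and heat shock held with an estimated correlation. Of 29 proteasome subunits, 18 rose, 1 fell and 10 did not pass (adjusted over the list alone, 21 rose and 1 fell; adjusted p = 7.82e-10, and adjusted p = 0.0095 with an estimated correlation), led by Psma6 of the core particle (2.36 ± 0.20) and Psmc5 of the regulatory particle (1.74 ± 0.20). Of 22 heat shock genes, 8 rose and 1 fell (adjusted over the list alone, 11 rose and 4 fell; adjusted p = 0.0028, and adjusted p = 0.0465 with an estimated correlation). The co-chaperone Dnaja1 rose by 2.11 ± 0.21. Replication genes rose, 12 of 36 with 0 falling (adjusted over the list alone, 14 rose and 1 fell; adjusted p = 5.39e-04, and adjusted p = 0.233 with an estimated correlation); Mcm3 rose by 2.03 ± 0.22 and the thymidine kinase Tk1 by 1.51. Cholesterol and fatty acid synthesis had 12 of 33 up and 1 down, the same adjusted over the list alone (adjusted p = 5.39e-04, and adjusted p = 0.126 with an estimated correlation). Fasn rose by 2.64 ± 0.23 and Scd1, a fatty acid desaturase, fell by 2.42. Oxidative phosphorylation had 16 of 36 up and 5 down (adjusted over the list alone, 18 rose and 5 fell; adjusted p = 5.39e-04, and adjusted p = 0.150 with an estimated correlation). Uqcrq of complex III rose by 3.15 ± 0.31 and Uqcrc2 of the same complex fell by 2.39. Ribosomal proteins had 9 of 50 up and 0 down (10 adjusted over the list alone; adjusted p = 5.39e-04, and adjusted p = 0.207 with an estimated correlation). Rps28 rose by 4.84 ± 0.25, but the ribosomal list lost its call after cyclic loess (0.484) and its direction turned with the span trend removed (0.959).

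Matrix genes were lower at 72 h: of 41, 21 fell, 2 rose and 18 did not pass (adjusted over the list alone, 24 fell and 3 rose; adjusted p = 6.38e-08, and adjusted p = 0.149 with an estimated correlation). Fn1, the fibronectin gene, fell by 2.87 ± 0.22, Thbs1, a matricellular protein, by 2.74 ± 0.25 and Lum, a collagen-binding proteoglycan, by 4.42 ± 0.48. Hypoxia and glycolysis genes were lower, 12 of 33 falling and 6 rising (adjusted over the list alone, 13 fell and 6 rose; adjusted p = 0.0087, and adjusted p = 0.207 with an estimated correlation); the hypoxia transcription factor Hif1a (-3.43 ± 0.35), its target Bnip3 (-3.41 ± 0.22) and the vessel growth factor Vegfa (-2.85 ± 0.26) fell. Adhesion genes were lower, 13 of 35 falling and 2 rising (adjusted over the list alone, 15 fell and 4 rose; adjusted p = 0.0471, and adjusted p = 0.307 with an estimated correlation). Cdh11, a mesenchymal cadherin, fell by 3.95 ± 0.36. The fibroblast markers had 5 of 12 down and 1 up (adjusted over the list alone, 6 fell and 3 rose; adjusted p = 0.0382, and adjusted p = 0.282 with an estimated correlation). Adhesion lost its call without control replicate 2 or 3 or knockdown replicate 1 or 3 (up to 0.0702), fibroblast markers without knockdown replicate 1 (0.0598), and both with the span trend removed (0.146 and 0.0589). Adhesion lost it too with the marker scores as covariates (0.118). Among lists without a call, the clock factors Arntl (-3.25 ± 0.43) and Clock (-2.59 ± 0.37) fell and Cry2 rose (1.73). The cell cycle inhibitors Cdkn1a (-2.89 ± 0.23) and Cdkn1b (-2.40 ± 0.30), the inflammatory enzyme Ptgs2 (-4.48 ± 0.33) and the muscle filament Des (-3.54 ± 0.26) fell.

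At 72 h 2951 sequences were higher and 4474 lower, 39.7% higher as deposited, 46.7% after cyclic loess and 46.8% with the span trend removed; the 7425 became 4605 with the marker scores as covariates and 4633 in fits on the compared groups alone. The differences followed the genomic span of the target: the median difference was 0.22 in the octile with the shortest spans and -0.34 in that with the longest, while at 24 h it ran from -0.15 to 0.15. Across 22084 target sequences, which are not independent replicates, Spearman's rank correlation between span and difference was 0.12 at 24 h, -0.01 at 48 h and -0.20 at 72 h. At 72 h 161 of 1120 genes with at least 2 called bright sequences had sequences called in opposite directions (14.4%), against 1 of 41 at 24 h (2.44%). Such genes included Hnrnpk and Srsf3, so the direction at 72 h belongs to the target sequence.

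**Figure D3:**
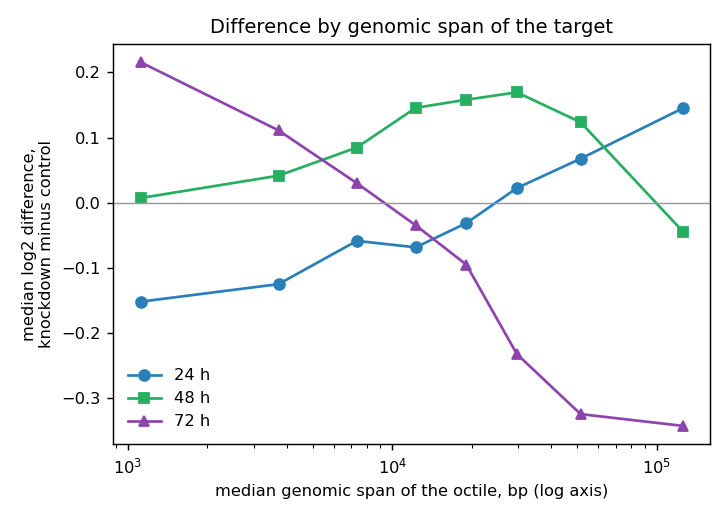
Median log2 difference, knockdown minus control, against the median genomic span (bp, log axis) of 8 equal groups of target sequences, with a line for each time. At 72 h the median runs from 0.22 at the shortest spans to -0.34 at the longest, and at 24 h from -0.15 to 0.15.

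Over all times the mean of the 3 differences was tested (8 knockdown and 9 control arrays), which can pass without a difference at each time. Krt8 (BC094009, chromosome 15, 101827139 to 101834737) rose by 6.26 ± 0.17 (adjusted p = 9.68e-12), from 6.33 to 12.59, Upk3b (BC120594, chromosome 5, 136514615 to 136520011) by 5.00 ± 0.16 (adjusted p = 1.12e-10) from 5.40, near the background, and Bmp4 (BC013459, chromosome 14, 47003394 to 47010251) by 4.55 ± 0.18 (adjusted p = 6.27e-10). Chrng (BC156729, chromosome 1, 89102395 to 89108061) fell by 3.68 ± 0.15 (adjusted p = 6.27e-10), and Tnnt3, troponin of fast muscle (L49466, chromosome 7, 149684747 to 149701908), by 2.76 ± 0.23 (adjusted p = 1.72e-06), with all 7 of its target sequences past the test in that direction. Krt7 (4.92), Lsr (4.52), Col14a1 (4.65, at least 21.2-fold over a control mean at the background), Pam (4.73) and Gpc3 (5.79) rose; Gpc3's difference of 4.13 at 24 h did not pass alone (adjusted p = 0.104), and its other sequence was near background. Aebp1 (-4.13), Tnc (-3.63), Crip1 (-3.30), the muscle transcription cofactor Vgll2 (-3.14), the matrix protein Efemp1 (-2.93), the imprinted RNA H19 (-2.79), Cntnap1 (-2.63) and the kinase Ptk2b (-2.52) fell. Uba1y (6.81) and Rpl7-ps8 (5.76) rose. In all, 2297 sequences were higher and 2095 lower, 52.3% higher as deposited, 48.1% above the median level and 85.5% with the marker scores as covariates; the 4392 became 338 with the marker scores as covariates, 1626 without the 4 arrays brightest in macrophage markers and 2134 without the arrays at 72 h.

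**Figure D4:**
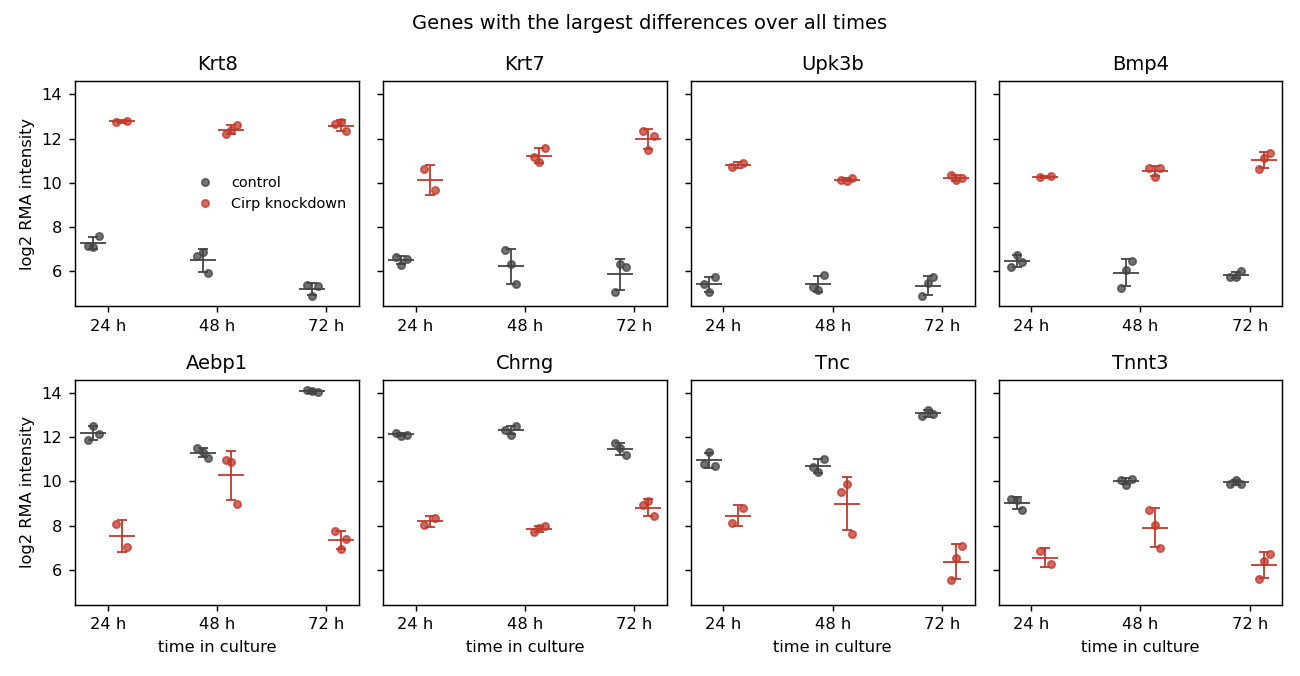
Log2 RMA intensity on each array against time for 8 of the genes with the largest differences over all times, control in grey and Cirp knockdown in red; horizontal lines are group means and bars the SD (n = 3, and n = 2 for the knockdown at 24 h). Krt8, Krt7, Upk3b and Bmp4 are higher and Aebp1, Chrng, Tnc and Tnnt3 lower in the knockdown at each time.

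Of the fixed lists, 9 passed over all times, and heat shock and proteasome held with an estimated correlation. Of 22 heat shock genes, 9 rose, 1 fell and 12 did not pass (adjusted over the list alone, 11 rose and 1 fell; adjusted p = 5.79e-06, and adjusted p = 0.0053 with an estimated correlation). Hspb1 rose by 1.66 ± 0.14, Dnaja1 rose by 1.29 ± 0.12 and Cryab, a small heat shock protein also abundant in muscle, rose by 1.63. Of 29 proteasome subunits, 11 rose and 0 fell (14 adjusted over the list alone; adjusted p = 7.13e-08, and adjusted p = 0.0112 with an estimated correlation). Psma6 rose by 1.35 ± 0.12. The mean difference of the proteasome list was 0.0013 at 24 h, 0.28 at 48 h and 0.83 at 72 h, where the list had fallen in the control cells. Cholesterol and fatty acid synthesis had 12 of 33 up and 1 down, the same adjusted over the list alone (adjusted p = 3.05e-05, and adjusted p = 0.0512 with an estimated correlation); Msmo1 rose by 2.03 ± 0.18 and Fasn by 1.62 ± 0.14. Replication genes had 11 of 36 up and 0 down (13 adjusted over the list alone; adjusted p = 3.05e-05, and adjusted p = 0.186 with an estimated correlation). Mcm3 rose by 1.10 ± 0.13. Oxidative stress genes had 10 of 29 up and 2 down (adjusted over the list alone, 11 rose and 3 fell; adjusted p = 0.0011, and adjusted p = 0.186 with an estimated correlation). Prdx3 rose by 2.22 ± 0.22 and the ferritin chain Ftl1 rose by 1.48. Matrix genes had 14 of 41 down and 1 up (adjusted over the list alone, 20 fell and 4 rose; adjusted p = 3.87e-07, and adjusted p = 0.153 with an estimated correlation). Fn1 fell by 1.30 ± 0.13, Lum fell by 2.20 and Col3a1 fell by 1.13. The fibroblast markers had 6 of 12 down and 1 up, the same adjusted over the list alone (adjusted p = 0.0242, and adjusted p = 0.259 with an estimated correlation). Clock genes had 4 of 20 down and 1 up, the same adjusted over the list alone (adjusted p = 0.0289, and adjusted p = 0.105 with an estimated correlation). Tef, a clock output factor, fell by 1.03 ± 0.20. Mitotic genes had 6 of 33 up and 2 down, the same adjusted over the list alone (adjusted p = 0.0467, and adjusted p = 0.533 with an estimated correlation). Clock and fibroblast lists lost their calls without knockdown replicate 1 at 24 h (0.058 and 0.0719), and the mitotic list after cyclic loess (0.0763). With the marker scores as covariates the clock (0.105) and mitotic (0.147) lists lost theirs, as they did without the 4 arrays brightest in macrophage markers (0.0921 and 0.218), and the mitotic list also with the span trend removed (0.0847). The mean differences at 24, 48 and 72 h were -0.74, 0.21 and -1.25 for matrix, -0.22, 0.67 and 0.53 for replication, -0.10, 0.64 and 0.62 for cholesterol synthesis and -0.29, 0.91 and 0.02 for mitotic genes, so these calls do not stand for the same difference at each time. The mitotic list also lost its call (up to 0.0956) without replicate 1 of the control at 24 or 72 h, either knockdown array at 24 h, knockdown replicate 1 or 2 at 48 h, or knockdown replicate 1 or 3 at 72 h.

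**Figure D5:**
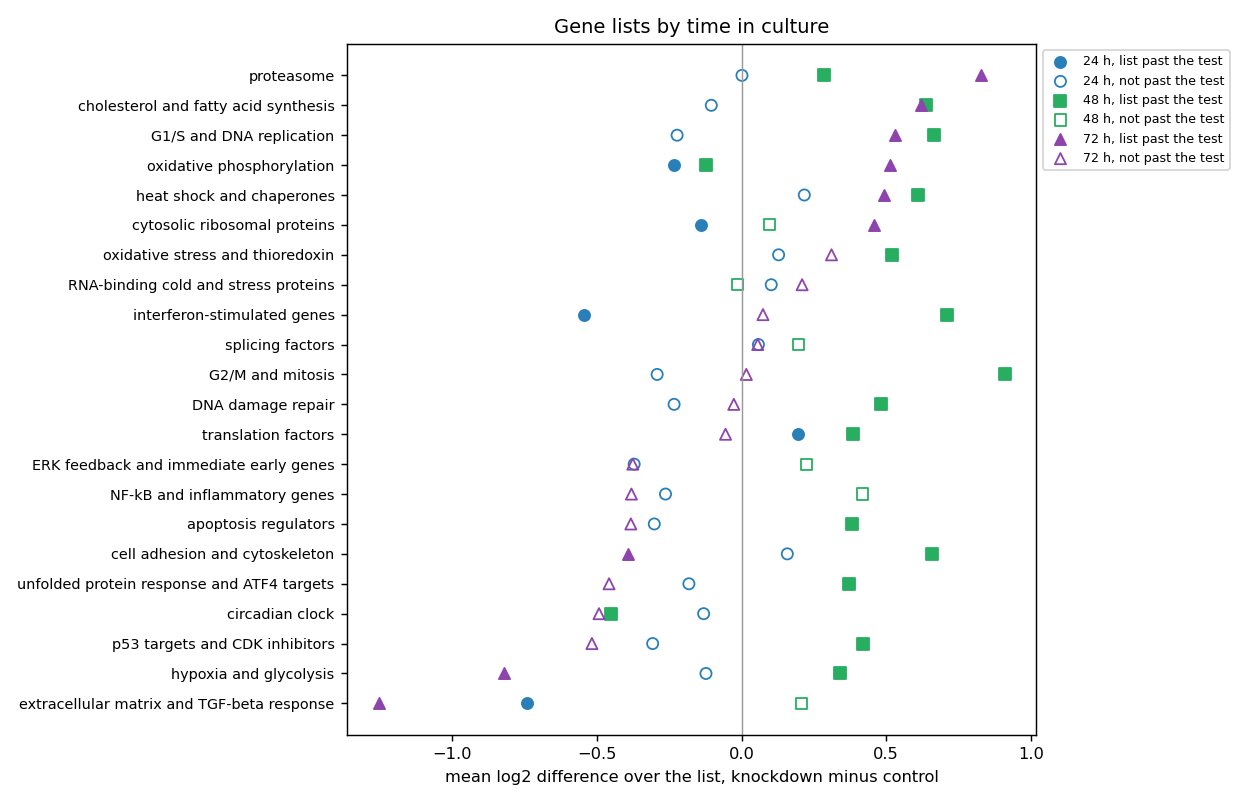
Mean log2 difference, knockdown minus control, over the members of 22 gene lists fixed beforehand (1 row per list) at 24, 48 and 72 h; filled markers are lists past the camera test with its preset correlation and open markers those not past it. Heat shock and proteasome genes are filled on the higher side at 48 and 72 h, and matrix genes on the lower side at 24 and 72 h; ribosomal proteins at 72 h turn direction with the span trend removed.

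The overlap asked whether the same sequences differed at each time, the times having separate control arrays. At all 3 times 168 target sequences (145 symbols) were higher and 21 (17 symbols) lower, against 0.822 and 0.370 for independent lists of these sizes; 133 of the 189 did not pass the interaction test. They included Krt7, Krt8, Upk3b, Bmp4, Hoxc10 and Chrng. The 189 became 112 without control replicate 3 at 24 h, 86 without knockdown replicate 1 at 24 h and 68 without knockdown replicate 2 at 24 h. They became 15 with the marker scores as covariates, 31 without the 4 arrays brightest in macrophage markers and 17 in fits on the compared groups alone. Between 48 and 72 h 669 were higher at both (100.6 expected) and 119 lower at both (99.1 expected), while 278 were higher at 48 h and lower at 72 h and 28 the reverse. Between 24 and 72 h 85 were higher and then lower and 12 the reverse. Across target sequences, which are not independent replicates, Pearson's r between the differences was 0.08 for 24 and 48 h, 0.08 for 48 and 72 h, and 0.16 for 24 and 72 h.

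The interaction tested whether the arm difference changed with time, and 5633 sequences (4369 symbols) passed. The 5 with the smallest p read higher in the knockdown at 24 and 48 h and lower at 72 h. Arhgap1 (AK079048, chromosome 2, 91490350 to 91512475) differed by 1.46 at 24 h, 1.34 at 48 h and -5.43 at 72 h (interaction adjusted p = 3.94e-08). Atxn2l, an RNA-binding protein of stress granules, differed by 1.64, 1.12 and -4.67 (1.51e-07). Pfkfb3 (1.70, 0.62 and -5.38), the Wnt effector Tcf7l2 (1.64, 0.48 and -4.99) and Zfp36l1, which speeds the decay of AU-rich mRNAs (1.66, 1.32 and -3.45), shared an interaction adjusted p of 3.74e-07. Other sequences of these genes did not all follow at 72 h: Arhgap1 BC006592 rose by 1.14, and the other Atxn2l sequence differed by -0.08. The interaction count became 92 without the arrays at 72 h, 3014 without those at 48 h and 1698 without the 4 arrays brightest in macrophage markers.

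Time in culture was compared within each arm. In control cells at 48 h against 24 h most of the 5 named genes that rose are known from brain, and they moved with the neuron marker mean, which was 9.89 to 10.03 at 48 h and 8.89, 7.13 and 6.87 at 24 h. Mbp rose by 5.95 ± 0.51 (adjusted p = 6.55e-05), at least 44.8-fold over a mean at the background at 24 h, Slc17a7 by 5.56 ± 0.56 (adjusted p = 1.76e-04), Prkcb by 5.35 and Mobp by 5.25; the neuroendocrine peptide gene Pcsk1n rose by 5.15 and lost its call without control replicate 2 or 3 at 24 h (up to 0.0548). Igf2bp1, a fetal RNA-binding protein, fell by 4.27 ± 0.43 (adjusted p = 1.76e-04), at least 16.4-fold to a mean at the background, Tgfbi by 3.69, Top2a, the topoisomerase of dividing cells, by 3.37 and the CDK inhibitor Cdkn1c by 3.32. Of 36 replication genes 9 fell and 0 rose (23 adjusted over the list alone; adjusted p = 2.66e-13, and adjusted p = 0.0445 with an estimated correlation), and of 33 mitotic genes 8 fell and 0 rose (17 adjusted over the list alone; adjusted p = 1.26e-11, and adjusted p = 0.0445 with an estimated correlation). In all, 1003 sequences were higher and 824 lower, 54.9% higher as deposited, 69.7% after cyclic loess and 66.8% with the span trend removed, but 41.3% above the median level, 26.7% in the brightest 25% alone and 45.9% with trend and robust settings, so no direction of the whole is given. The 1827 became 751, 817, 1050, 1001 and 938 without, in turn, control replicates 2 and 3 at 24 h and 1, 2 and 3 at 48 h, and 124 without the 4 arrays brightest in macrophage markers. With the marker scores as covariates limma called 0, with 3038 at an unadjusted p under 0.05.

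In control cells at 72 h against 24 h, Pfkfb3 rose by 4.66 ± 0.27 (adjusted p = 1.51e-06), Pgm5, a phosphoglucomutase relative found at muscle adhesions, by 4.84 ± 0.33 (adjusted p = 2.57e-06), the ubiquitin ligase Pdzrn3 by 4.93, Paqr6 by 4.45 and Iqsec2 by 4.30, at least 17.7-fold over a mean at the background. Kif23, a kinesin of cytokinesis, fell by 2.76 ± 0.25 (adjusted p = 1.76e-05), Erh by 2.77, Washc1 by 2.84, Swi5 by 2.82 and Wbp1l by 2.75. Of 29 proteasome subunits 17 fell and 0 rose (21 adjusted over the list alone; adjusted p = 3.91e-15, and adjusted p = 0.0017 with an estimated correlation), of 36 replication genes 21 fell and 0 rose (26 adjusted over the list alone; adjusted p = 1.93e-17, and adjusted p = 0.0143 with an estimated correlation), and of 22 heat shock genes 9 fell and 1 rose (adjusted over the list alone, 13 fell and 2 rose; adjusted p = 7.36e-05, and adjusted p = 0.0084 with an estimated correlation). The proteasome, replication and heat shock genes that were higher in the knockdown at 72 h were thus compared with controls in which these lists had fallen. Hypoxia and glycolysis genes rose, 12 of 33 with 2 falling (adjusted over the list alone, 13 rose and 3 fell; adjusted p = 0.0031, and adjusted p = 0.166 with an estimated correlation). Bnip3 rose by 3.09 and Vegfa rose by 2.31. Matrix genes rose, 10 of 41 with 0 falling (11 adjusted over the list alone; adjusted p = 2.62e-04, and adjusted p = 0.227 with an estimated correlation). Fn1 rose by 1.52. In all, 2304 sequences were higher and 2387 lower, 49.1% higher as deposited, 58.6% after cyclic loess, 57.6% with the span trend removed and 45.5% above the median level; the 4691 became 917 with the marker scores as covariates and 828 without the 4 arrays brightest in macrophage markers.

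In knockdown cells at 48 h against 24 h, 70 sequences were higher and 67 lower. Upk1b, a urothelial surface protein, rose by 2.47 ± 0.30 (adjusted p = 0.0099) and Sprr2f, a cornified envelope protein, by 2.31 ± 0.27 (adjusted p = 0.0082), and Atxn2l fell by 2.18 ± 0.25 (adjusted p = 0.0082). Slc29a1 (2.84), Aebp1 (2.72) and Tcf24 (2.29) rose, and the developmental gene Mab21l2 (-3.02), the zinc finger gene Tshz2 (-2.63), Tenm2 (-2.59, at least 5.56-fold to a mean at the background) and Endod1 (-2.19) fell. All 10 lost their calls without replicate 2 at 24 h, and the 137 became 29 without replicate 1 at 24 h, 0 by limma without replicate 2 at 24 h (3392 at an unadjusted p under 0.05), and 6, 6 and 35 without replicates 1, 2 and 3 at 48 h. With the marker scores as covariates limma called 0, with 3443 at an unadjusted p under 0.05. Of the 137, 51.1% were higher; the share was 36.9% with the span trend removed. In knockdown cells at 72 h against 24 h, 1000 were higher and 2221 lower, 31.0% higher as deposited, 51.7% after cyclic loess and 49.7% with the span trend removed. Selenbp1, a selenium-binding protein, rose by 3.46 ± 0.37 (adjusted p = 1.43e-04) and Tnnc1, troponin of slow and cardiac muscle, by 3.42 ± 0.42 (adjusted p = 2.87e-04), with Calml4 (3.31), the epithelial ion transport regulator Fxyd3 (3.11) and Rin3 (3.03). Arhgap1 fell by 4.32 ± 0.25 (adjusted p = 1.23e-06), Atxn2l fell by 4.01 ± 0.25 (adjusted p = 2.28e-06) and Tcf7l2 fell by 3.82 ± 0.28 (adjusted p = 1.18e-05). Arhgap23 (-3.61) and the splicing GTPase Eftud2 (-3.59) fell as well. The 3221 became 1270 without replicate 1 and 1276 without replicate 2 of the knockdown at 24 h, and 247 with the marker scores as covariates. In fits on the compared groups alone limma called 0, with 0.1354 as the lowest adjusted p and 6144 at an unadjusted p under 0.05.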

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

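The tests in this part were chosen after the results they measure had been seen, apart from the test of the authors' normalization on the neuron markers, which was written down first. The difference between the arms changed with time in 5633 target sequences by the interaction test. The smallest adjusted p-values were those of Arhgap1 (3.94e-08), Atxn2l (1.51e-07), Pfkfb3 (3.74e-07), Tcf7l2 (3.74e-07) and Zfp36l1 (3.74e-07), each higher in the knockdown at 24 h and lower at 72 h. The row of random-sequence probes, which reads no gene, had a mean log2 intensity of 5.52 on the knockdown arrays at 72 h (5.50 to 5.54), against 5.43 on the control arrays at 72 h (5.41 to 5.45) and 5.26 to 5.34 in the other groups.

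Brain and macrophage transcripts differed between arrays of one group. The within-group SD of the macrophage list fixed beforehand was 1.27 times the highest of 1000 random gene sets of its size and level. That of the 21 neuron markers not among the named genes was 2.54 times its highest. In a second draw the highest set was at 0.47 against 0.50 for the macrophage list. Of the 28 fixed lists, 6 lay above all their sets. Random sets are not picked to move together, so this cannot test arm and time in culture alone. Cyclic loess of the normalized values left 86.9% of the range of the neuron mean among control arrays at 24 h. It cannot test the authors' normalization. RNA of brain tissue and of macrophages on some arrays is a candidate explanation that stays open: 60.9% of 46 neuron, oligodendrocyte and astrocyte markers were at least 1 log2 unit higher on the control arrays at 48 h than at 72 h, short of the 3 in 4 set as its mark. Among abundant brain transcripts, Mbp read 11.32 against 5.66 and Slc17a7 11.12 against 5.29, while Gfap and Sox10 did not differ by 1 unit; the macrophage gene Lyz2 read 11.24 and 10.64 in control replicates 2 and 3 at 24 h against 7.47 in replicate 1. No label names such cells, and no other biological explanation was tested.

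The 189 target sequences called in one direction at all 3 times, keratins and muscle genes among them, were set against 3 explanations. With both marker means as covariates the median size of the difference over all times was 102% of that without (quartiles 95.3% to 110%). Neuron and macrophage differences changed sign with time and those of the 189 did not, so this cannot test RNA behind those markers. By the test first in mind 143 of the 189 (75.7%) kept a call. That was not the call at all 3 times, which far fewer sequences had with these covariates. The median SE rose from 0.24 to 0.52 (9 residual degrees of freedom), and how far this ended calls was not tested. With any 1 array left out at least 68 sequences were called in one direction at all 3 times. That cannot test a single mislabelled array, which enters the comparison at 1 time only. The knockdown itself and any other difference between the 2 cell populations, such as descent from a different cell, cannot be told apart with 1 population per arm; 133 of the 189 did not pass the interaction test.

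At 72 h the differences followed genomic span. Cyclic loess left 89.1% of Spearman's correlation between span and difference, but likewise cannot test the authors' normalization as the cause of that trend. Transcript length or RNA quality as its cause stays open at a correlation of -0.20, since neither was used here. Of the 7425 called target sequences, 91.8% kept call and direction after cyclic loess and 83.2% with the trend removed. Its medians (0.22 to -0.34) were too small for this to test a bias that follows span. For lists the trend stays open. Of the 10 called at 72 h, 70% kept call and direction, between the marks set for and against it. An effect of the knockdown at 72 h stays open as well and was not tested apart from it.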

How the results depend on the processing

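Of the settings added after seeing the data, leaving out the 4 arrays does not isolate macrophage markers. It left 1 array per group touched, that with the highest neuron mean. With each array left out in turn the counts ranged from 6079 to 7128 at 72 h, from 4281 to 6005 in the interaction and from 3001 to 4587 over all times. The same ranges were 98 to 510 at 24 h, 1122 to 2796 at 48 h, 751 to 1720 and 3223 to 3821 for control cells at 48 and 72 h against 24 h, 0 to 35 and 1270 to 2970 for knockdown cells, 68 to 185 for the overlap, 63 to 76 for the list tests, and -0.94 to -0.81 for Cirbp. Median centring, cyclic loess, 1 target sequence per gene, the series-wide table, fry and the span correction moved none of the counts of genes or lists by more than 1.5 times. Of 12806 values of 631 named gene results, 11237 kept direction and side of the threshold, 1534 lost and 14 gained a call, 21 uncalled ones moved and 0 called ones reversed by limma; of 38 values of Cirbp at single times, 27 kept both and 11 lost the call.

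With the marker means as covariates the counts were 67 at 24 h, 19 at 48 h, 4605 at 72 h, 338 over all times, 3308 in the interaction, 0 and 917 in control cells at 48 and 72 h, 0 and 247 in knockdown cells, 15 in the overlap and 40 lists. Cirbp read -1.08 (adjusted p = 0.157, range over alternatives 4.07e-04 to 0.157). Interferon-stimulated genes reversed at 24 h (0.855), at 48 h (0.659) and in control cells at 48 h (0.192), as did matrix genes there (0.785). Macrophage and leukocyte markers reversed at 24 h (0.998), but a covariate held such markers. Without the 4 arrays the counts were 40 at 24 h, 195 at 48 h, 1626 over all times, 1698 in the interaction, 124 and 828 in control cells, 3 and 1973 in knockdown cells and 31 in the overlap, and Cirbp read -0.77 (adjusted p = 0.0527). Interferon-stimulated genes reversed at 24 h (0.753), at 48 h (0.933) and in control cells at 48 h (0.392). How much of the loss follows from the covariates' larger median SE (0.52 against 0.24 over all times) or from fewer arrays was not tested.

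Without the 72 h arrays the counts were 2134 over all times and 92 in the interaction, and without the 48 h arrays the interaction had 3014. Ribosomal proteins in control cells at 72 h reversed after cyclic loess (0.419) and with the span trend removed (0.0164), and in the knockdown at 72 h with the span trend removed (0.959); the cause was not tested. Above the median level the counts were 1312 at 24 h, 2754 in control cells at 48 h, 832 in knockdown cells at 48 h and 338 in the overlap, and with the brightest 25% alone 2058 at 24 h and 1734 in knockdown cells at 48 h. Trend and robust settings gave 1626 at 24 h, 3137 in control cells at 48 h and 1289 in knockdown cells at 48 h. Array weights gave 4394 at 48 h and 500 in knockdown cells at 48 h. Fits on the compared groups alone, which have fewer residual degrees of freedom, gave 20 at 24 h, 4633 at 72 h, 963 in control cells at 48 h and 17 in the overlap, and limma called 0 in knockdown cells at 48 h and 0 at 72 h, with 5501 and 6144 at an unadjusted p under 0.05. The marker means as covariates left 3038 and 3443 at that level in control and knockdown cells at 48 h, and leaving out knockdown replicate 2 at 24 h left 3392. The replicate block gave 320 at 24 h and 22 in knockdown cells at 48 h, and also ended the call of Cirbp at 72 h (adjusted p = 0.0644). A minimum log2 difference of 1 left 1696 over all times, which follows from the filter, and the estimated correlation left 12 lists. For the other moves the cause was not tested.

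A block for slide or scan, planned beforehand, was not run, since neither is given in the sources used here. Signal over background limits the calls: 27.4% to 33.1% of the target sequences on an array lay at least 4-fold above the random-sequence row, and a gene near it cannot be told from one that the mouse probes do not read.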

Other observations

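The tests in this part on the 10 added lists, and the counts of other splits for the target sequences and for the lists over all times, were chosen after the results had been seen; the counts of splits for the lists at single times and in control cells were not. Where a pair of p-values stands in parentheses, the first is the adjusted p and the second the adjusted p with an estimated correlation. The added lists were built after the data had been seen, and several hold members already seen among the largest differences, so their p-values are no independent test of direction. Of 13 markers of mesothelium, the lining of body cavities, 4 rose at 24 h (adjusted p = 5.64e-05; adjusted p = 0.008 with an estimated correlation), 7 rose and 2 fell at 48 h (2.88e-06; 0.0042), 7 rose at 72 h (2.13e-05; 0.0087), and over all times 7 rose and 1 fell (9.81e-08; 0.0023). Their mean was 7.98 to 8.79 on the knockdown arrays and 5.95 to 7.01 on the control arrays. Of 26 genes of simple epithelium and cell junctions, which share Krt7, Krt8, Krt18 and Krt19 with the mesothelium list, 7 rose and 3 fell over all times (2.04e-04; 0.0053). Krt19 rose by 1.66 ± 0.23 over all times, and Krt18, the usual partner of Krt8, fell by 1.05 ± 0.26 (adjusted p = 0.0186), a call lost without knockdown replicate 2 at 24 h (0.0757).

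Of 28 skeletal muscle genes, 5 fell at 24 h (adjusted p = 3.57e-07; adjusted p = 0.008 with an estimated correlation), 5 at 48 h (2.73e-04; 0.0471) and 13 at 72 h with 1 rising (4.04e-05; 0.0398), and over all times 13 fell and 1 rose (8.85e-08; 0.006). Their mean was 6.72 to 7.28 on the knockdown arrays and 7.57 to 8.40 on the control arrays; Des, a muscle filament, fell by 2.09 ± 0.15 over all times. Of 31 HOX genes, which pattern the body axis, 11 rose and 1 fell over all times (adjusted p = 3.13e-06; adjusted p = 0.174 with an estimated correlation). Their mean overlapped between the arms, 6.45 to 8.14 on the control and 7.27 to 8.44 on the knockdown arrays; control replicate 1 at 24 h, which had the highest neuron mean of its group, read 8.14 against 7.10 and 6.98 in replicates 2 and 3. Hoxc10 and Hoxd9 were higher at all 3 times.

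Among the lists fixed beforehand, those of immune and stress signalling did not pass over all times. NF-kB and inflammatory genes had 1 of 33 up and 2 down (adjusted p = 0.477), interferon-stimulated genes 0 of 31 up and 1 down (0.503), and ERK feedback genes 3 of 26 up and 6 down (0.0884), among them Etv4 (1.69), Fosl2 (-1.29) and Egr3 (-1.13). RNA-binding cold and stress proteins, the family nearest to Cirp, had 3 of 19 up, among them Rbmx (0.93), and 1 down (0.249). Splicing factors had 6 of 37 up and 2 down (0.0928), translation factors 7 of 30 up and 1 down (0.0588), and the unfolded protein response 3 of 30 up and 3 down (0.441). Targets of p53 had 1 of 25 up and 2 down (0.461), apoptosis regulators 2 of 26 up and 0 down although the median was lower at -0.11 (0.823), hypoxia and glycolysis genes 4 of 33 up and 9 down (0.217), and adhesion genes 5 of 35 up and 5 down (0.441). The median and the mean differed in sign for ribosomal proteins (9 of 50 up and 1 down, median -0.03, mean 0.14, 0.282), oxidative phosphorylation (6 of 36 up and 5 down, -0.06 and 0.05, 0.760) and DNA repair (6 of 33 up and 3 down, -0.05 and 0.07, 0.458). They differed as well for matrix genes at 48 h (-0.04 and 0.21), for RNA-binding cold proteins at 48 h (0.11 and -0.02) for ribosomal proteins at 48 h (-0.01 and 0.10) and for DNA repair at 72 h (0.19 and -0.03), none past the test. At 24 h the test's direction was higher while median and mean were below 0 for hypoxia and glycolysis (-0.24 and -0.12, adjusted p = 0.987) and cholesterol synthesis (-0.04 and -0.10, adjusted p = 0.987).

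Of the cell type markers fixed beforehand, kidney tubule markers, which include Krt8, Krt18 and Krt19, had 2 of 15 up and 1 down over all times (adjusted p = 0.0884). Myofibroblast and smooth muscle markers had 2 of 7 down (0.085), endothelium markers 0 of 10 past the test (0.434) and macrophage and leukocyte markers 0 of 9 (0.232), with 2 down adjusted over the list alone. Olfactory receptors, the background list, had 1 of 14 down, Olfr706 (0.834; median 0.03, mean -0.06). Of the added lists at 48 h, 8 of 22 neuron markers fell (adjusted p = 1.49e-10; adjusted p = 0.0761 with an estimated correlation), as did 5 of 12 oligodendrocyte markers (6.81e-09; 0.0044) and 6 of 12 astrocyte markers (4.73e-08; 0.033). The longer macrophage list of 19 was lower at 24 h (3.62e-05; 0.133) with 0 past the test by limma, and MHC class I genes were lower at 24 h (0 of 14; 0.0033; 0.256) and higher at 48 h (1 of 14; 2.73e-04; 0.136). Erythroid markers did not pass over all times (1 of 12 down; 0.843).

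In control cells other lists changed between 24 and 48 h. Lower were p53 targets (2 of 25 fell; adjusted p = 6.88e-04; adjusted p = 0.114 with an estimated correlation), apoptosis regulators (3 of 26; 0.0022; 0.0838), translation factors (1 of 30; 2.44e-04; 0.117), splicing factors (2 of 37; 0.0035; 0.210; 0.0515 after cyclic loess), the unfolded protein response (2 of 30; 0.0035; 0.159), heat shock genes (2 of 22; 0.0035; 0.0445), DNA repair (5 of 33; 6.88e-04; 0.0871) and adhesion (3 of 35; 2.04e-04; 0.0871). Oxidative phosphorylation was higher with 0 of 36 past the test (3.56e-04; 0.0871). The neuron and macrophage markers moved in this comparison too, and with their means as covariates p53 targets (0.340), apoptosis (0.176), splicing factors (0.176), the unfolded protein response (0.192), heat shock (0.154) and adhesion (0.192) lost their calls. Without the 4 arrays brightest in macrophage markers apoptosis (0.0609), the unfolded protein response (0.199) and heat shock (0.0563) lost theirs, and with the span trend removed splicing factors (0.402), the unfolded protein response (0.118) and heat shock (0.0825) did. Calls that some array decided were those of clock genes, higher with 3 of 20 up (0.0231; 0.0871), lost without replicate 1 at either time (up to 0.0598), and of ribosomal proteins, higher with 0 of 50 past the test (0.0147; 0.325), lost without replicate 1 at 24 h or 3 at 48 h (up to 0.0886). ERK feedback genes were lower with 4 of 26 down (0.0259; 0.273), lost without replicate 2 or 3 at 24 h or 3 at 48 h (up to 0.157). Interferon-stimulated genes were lower with 0 of 31 past the test (0.0209; 0.458), lost without replicate 2 or 3 at 24 h or 1 or 3 at 48 h (up to 0.200), and matrix genes with 1 of 41 down (0.0115; 0.393), lost without replicate 2 or 3 at 24 h (up to 0.125).

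Between 24 and 72 h in control cells, lower lists were RNA-binding cold proteins (7 of 19 fell; adjusted p = 1.26e-04; adjusted p = 0.0629 with an estimated correlation), mitotic genes (11 of 33; 6.9e-08; 0.0629), splicing factors (16 of 37 with 3 up; 5.24e-06; 0.0629), translation factors (6 of 30 with 1 up; 0.0042; 0.227), oxidative phosphorylation (10 of 36 with 1 up; 4.87e-05; 0.0629), cholesterol synthesis (8 of 33 with 1 up; 0.0145; 0.186; 0.0802 after cyclic loess) and DNA repair (5 of 33 with 1 up; 0.01; 0.186). Translation factors lost their call after cyclic loess (0.323), with the span trend removed (0.327) and with the marker means as covariates (0.0812), DNA repair with the covariates (0.275), and oxidative phosphorylation (0.283) and cholesterol synthesis (0.0799) with the span trend removed. Ribosomal proteins were lower with 5 of 50 down (0.0218; 0.341), lost without replicate 3 at 24 h (0.0702) and without the 4 arrays brightest in macrophage markers (0.177); they turned after cyclic loess (0.419) and, past the threshold, with the span trend removed (0.0164). Oxidative stress genes were lower with 6 of 29 down and 1 up (0.0449; 0.394), lost without replicate 2 or 3 at 24 h or 2 at 72 h (up to 0.127) and after cyclic loess (0.419). Fibroblast markers were higher with 4 of 12 up (0.0237; 0.239), lost without replicate 1 at 24 h (0.119) and with the marker means as covariates (0.243). The cell cycle inhibitors Cdkn1a (2.55) and Cdkn1b (1.95) rose, and the clock repressor Nr1d1 rose by 1.79 ± 0.21.

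Other splits of the same arrays into groups of the same sizes were run for single comparisons with at least 3 arrays per group, and for the arms over all times and the interaction, which include the knockdown group at 24 h with 2 arrays. Over all times (4392, highest other 2613) and in the interaction (5633, highest other 5058) only the real 1 of 100 splits had as many. This assumes independent arrays, which is not known. Chance cannot be excluded for the 9 lists over all times (highest other 13, 16 of 100). For single comparisons the 10 splits are too few for a share under 0.05: the real and the highest other counts were 2484 and 0 at 48 h, 7425 and 2 at 72 h, 1827 and 1 for control cells at 48 h, 4691 and 1 for control cells at 72 h, and for lists 16 and 15, 10 and 3, 16 and 13, and 15 and 9 in the same order. In each of these the real split was the 1 with as many.

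Of the 17 arrays, 5 correlated best with an array outside their own group, across target sequences that are not independent replicates: control replicates 1 and 2 at 24 h, knockdown replicate 3 at 48 h, and knockdown replicates 1 and 3 at 72 h, with r from 0.905 to 0.948. The 3 target sequences of Uba1y were all higher in the knockdown, while those of Uba1, BC058630 and BC145984, read 13.37 and 13.64 in control and 13.93 and 13.72 in knockdown cells. Rpl7-ps8 read 7.13 in control and 12.90 in knockdown cells over all times.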
